A study of Nothobranchius furzeri and Iconisemion striatum and Callopanchax occidentalis with 18 samples.

How the data were processed

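Whole embryos at the somite stage were used, per the labels, and libraries were made from total RNA with Illumina's TruSeq small RNA kit, per the labels' protocols. The reads were quality filtered, trimmed of adapters, kept at lengths of 18 to 33 nt and aligned, per the file headers. CASAVA 1.8.2, bcl2fastq 1.8.3 and Bowtie 1.0.0 and 1.1.2 are named, per the submitters' processing notes. The miRNA sequences that served as the alignment reference, the mismatches allowed and the treatment of reads matching several miRNAs are not given in the sources used here. As 8 species were counted against the same list of 291 mature miRNAs, a species whose sequence differs from that reference can lose counts, and reads of near-identical family members can be shared. The counts of miR-126a-5p and miR-126b-5p were close to each other over the libraries (mean log2 ratio 0.10, SD 0.16), so they are uncertain and are not reported singly. Genomic positions of the miRNAs were not analysed here.

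The authors deposited raw counts per mature miRNA for each library, and RPM values that equalled these counts divided by the library's total (100% of values within a tolerance of 0.001), so the counts were used throughout. The last line of the count table, a total that names no miRNA, was left out; it was equal to the sum of the others. The table also held 2 columns matching no sample, which were left out. Sequencing runs were read from the library names of the deposited table: 8 libraries of lane 1, 9 of pool 3 and 1 of pool 2. Of all 18 to 33 nt reads, between 1.43% and 77.3% per library were counted on miRNAs. The N. furzeri libraries not in diapause were all of strain MZM0410 and pool 3. Those in diapause were of strain MZM0403 (replicate 1, lane 1), MZM0410 (replicate 2, lane 1, and replicate 3, pool 3, after 2 weeks of diapause) and GRZ x MZZW (replicate 4, pool 3, after 1 month, and replicate 5, pool 2, after 2 months), so strain, run and duration were partly confounded with diapause. Replicate numbers follow the order of the samples and pair nothing. No pair of replicate libraries agreed within counting noise, as sequencing of a single library more than once would, so none was treated as a repeat of another.

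Groups were taken from the labels. The comparisons, tests, lists, rule for named miRNAs and most alternatives were fixed before the data were examined. In R 4.3.3, edgeR 4.0.16 was used with filterByExpr, TMM scaling and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with their standard errors, and CPM values are TMM scaled within each comparison. For the comparison of annual with non-annual species, counts were summed per species and the species was the replicate. The 27 lists of miRNA families and tissue miRNAs were tested as sets with fry of limma 3.58.1 where at least 2 members were measured. They were also tested as shares of all counts with a two-sided exact permutation test. The shares were per library, and in the comparison of annual with non-annual species per species from the summed counts. fry's directional test asks whether the members move one way on balance, and it does not compare them with other miRNAs. camera was run with an estimated correlation and with a preset correlation of 0.01. Single-library shares have 95% Wilson intervals, and a count of 0 allows up to 3 counts. miRNAs were named if they were among the 10 higher or 10 lower with the largest log2 fold change at an adjusted p under 0.05, an average of at least 50 CPM and no overlap between groups, if they were the 2 most abundant members of a list that passed its test, or if they were members of the miR-430, miR-19, miR-29 or miR-101 lists with an average of at least 50 CPM.

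The alternatives were DESeq2's size factors, library totals only, TMM without the 10 most abundant miRNAs, no filter, at least 50 CPM, the Wald test of DESeq2 1.42.0, each library or species left out, strain MZM0410 only, strain as a covariate, N. furzeri not in diapause standing for its species, A. leohoignei left out or counted as annual, limma on species means and every library as a replicate. Pool 3 only, lane 1 only and run as a covariate were added after the data were examined. Data were simulated from these libraries (5 runs, 40 of 291 miRNAs changed, each averaging at least 50 CPM). Changes in less abundant miRNAs, such as miR-29a, miR-29b and miR-210-3p in N. furzeri, were not simulated. The test called 48% of 4-fold and 5% of 2-fold changes for N. furzeri in and out of diapause. It called 43% and 5% for N. furzeri against A. striatum, and 3% and 1% for the comparison of species. Of all calls, 1 of 54, 0 of 48 and 3 of 7 were of unchanged miRNAs, and none had the wrong direction.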

Results

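Small RNAs of whole killifish embryos at the somite stage, when the body segments form, were sequenced in 18 libraries from 8 species. Annual killifish live in pools that dry out, and their embryos can enter diapause, a reversible arrest of development. Nothobranchius furzeri, an annual species, gave 5 libraries of embryos in diapause and 3 libraries of embryos not in diapause. Callopanchax occidentalis and Nematolebias papilliferus, both labelled annual, gave 1 library each, in diapause. The 5 species labelled non-annual were not in diapause: Aphyosemion striatum (named Iconisemion striatum as the organism in the labels) with 4 libraries, and Austrofundulus leohoignei, Aplocheilus lineatus, Rivulus cylindraceus and Epiplatys dageti monroviae with 1 library each. The table listed 291 mature miRNAs, the short RNAs that guide repression of messenger RNAs, and each library held between 197 and 249 of them.

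The counts assigned to miRNAs totalled between 371908 (R. cylindraceus) and 4177400 (N. furzeri not in diapause, replicate 1). The N. furzeri diapause libraries held 1391848, 579183, 2551501, 4103430 and 1250129 counts in replicates 1 to 5, and the other N. furzeri libraries held 4177400, 1285872 and 2545989. The A. striatum libraries held 1467661, 2406413, 1077129 and 751598. The other single libraries held 758683 (C. occidentalis), 926161 (N. papilliferus), 1090382 (A. leohoignei), 1167260 (A. lineatus) and 524382 (E. dageti monroviae). A miRNA at 3 counts, the upper limit that a count of 0 allows, lay between 0.718 and 8.07 RPM (reads scaled to the total of each library), depending on the library. Intervals and floors cover counting error only. The labels do not say that replicate libraries came from separate clutches, so p-values measure the spread between these samples, which may be technical.

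miR-10b-5p, encoded within the Hox gene clusters that pattern the body axis, was the most abundant miRNA in every library except replicates 3 and 4 of A. striatum and the R. cylindraceus library, where miR-430a-3p was. miR-430 is the teleost family that clears maternal messenger RNAs in the early embryo. The miR-10 and miR-196 miRNAs of the Hox clusters together took 80.8% ± 10.1 (SD, n = 5) of counts in N. furzeri in diapause, 74.0% ± 9.49 (n = 3) in N. furzeri not in diapause and 38.0% ± 17.03 (n = 4) in A. striatum. In R. cylindraceus they took 6.03% (95% Wilson interval 5.95 to 6.11%). The miR-430 family took 65.5% (65.4 to 65.7%) of the counts in R. cylindraceus and 0.840% (0.820 to 0.861%) in C. occidentalis.

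**Figure D1:**
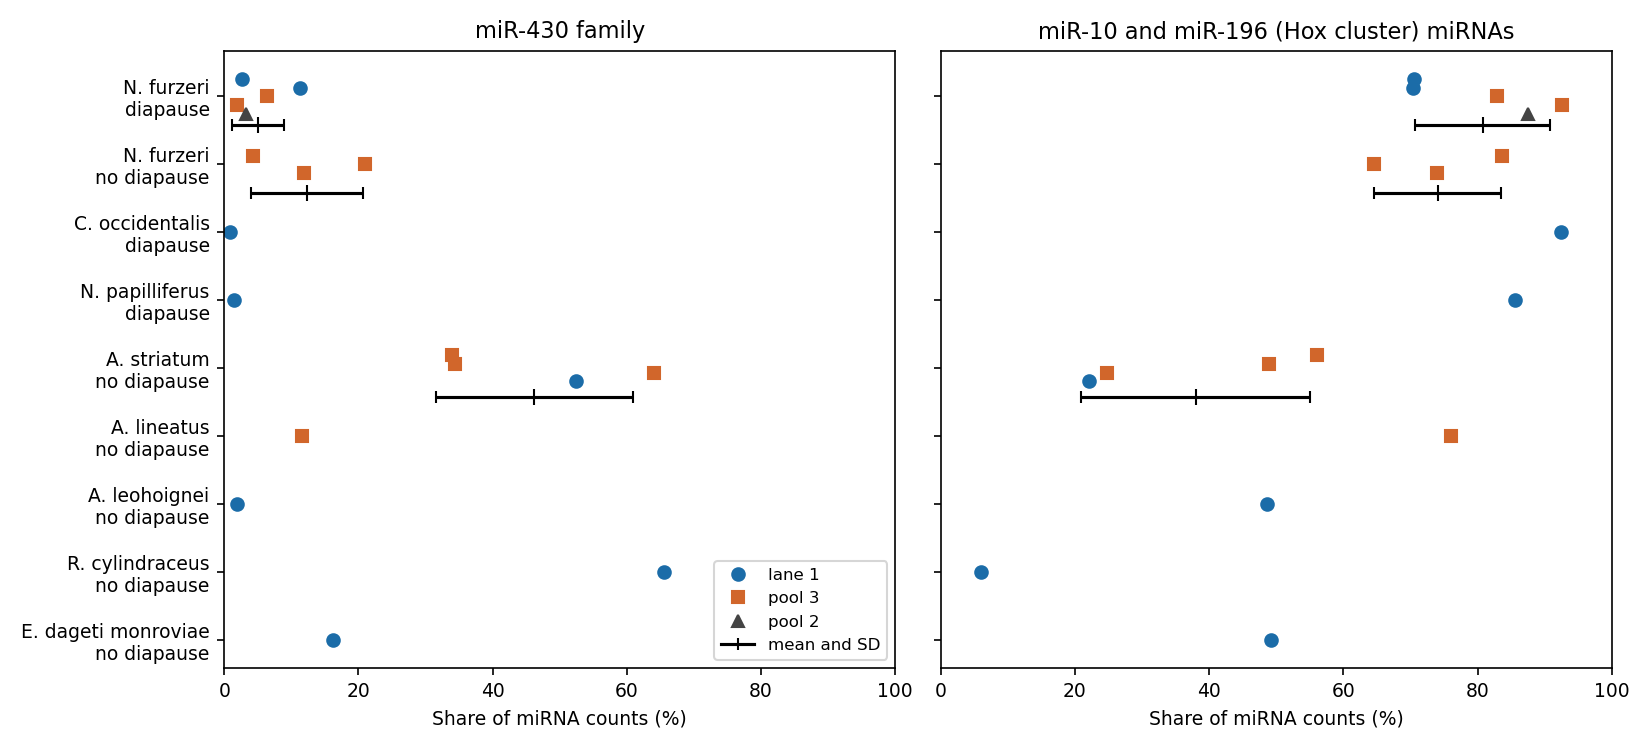
Share of miRNA counts (%, x axis) taken by the miR-430 family (left) and by the miR-10 and miR-196 miRNAs of the Hox clusters (right) in each library, by species and diapause state (y axis). Points are libraries, marked by sequencing run (lane 1, pool 3 or pool 2), and black bars give mean and SD for groups of at least 3 libraries; the miR-430 share averaged 46.2% in the 4 A. striatum libraries and 5.07% in the 5 N. furzeri diapause libraries.

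N. furzeri embryos in diapause were compared with N. furzeri embryos of the same stage that were not in diapause. miR-29a, of a family known to repress collagen and other matrix genes, averaged 39.1 ± 17.4 CPM (scaled counts, SD, n = 5) in diapause and 10.6 ± 5.50 CPM (n = 3) outside it, a log2 fold change of 1.86 (SE 0.53). miR-29b averaged 18.5 ± 5.21 CPM against 7.72 ± 2.28 CPM, a log2 fold change of 1.28 (SE 0.44). With TMM scaling every diapause library lay above every other library for both members, but with library totals only miR-29a in diapause replicate 4 (13.9 RPM) lay below replicate 1 of the embryos not in diapause (16.5 RPM). Together they rose in diapause by the directional set test fry of limma (two-sided, adjusted p = 0.0112 over 25 lists), while camera gave an adjusted p = 0.571 with an estimated correlation. Both members passed when adjusted over the list alone, as did 2 members each of the miR-19 and miR-30 lists and 1 of the hypoxia and stress list. That adjustment does not cover the choice of list. Neither miR-29 member passed over all miRNAs (edgeR adjusted p = 0.210 and 0.224). The fry adjusted p was 0.840 with library totals only and 0.314 within pool 3, and it lay between 0.0578 and 0.140 without diapause replicate 1, 4 or 5 or without replicate 2 or 3 of the embryos not in diapause.

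The miR-430 family took 5.07% ± 3.87 (SD, n = 5) of counts in diapause and 12.4% ± 8.32 (n = 3) outside it, a difference of -7.30 percentage points (two-sided exact permutation p = 0.125, adjusted p = 0.941 over 27 lists). Without replicate 1 of the embryos not in diapause the difference was -11.3 points (exact p = 0.0476), without their replicate 2 it was -3.01 points (exact p = 0.476), within strain MZM0410 -3.52 points (exact p = 0.7) and within pool 3 -8.21 points (exact p = 0.3), the last 2 with a smallest p possible of 0.1. Each of the 4 miR-430 members tested had a negative log2 fold change under every scaling tried, among them miR-430a-3p (-1.29, SE 0.62), miR-430c-3p (-1.59, SE 0.74) and miR-430a-5p (-1.04, SE 0.41), but the family did not pass fry (adjusted p = 0.761). Without replicate 2 of the embryos not in diapause these values were -0.52, -0.77 and -0.43. Of the miR-17-92 clusters, known to drive proliferation, 12 of 12 members without miR-19 had a negative value with TMM scaling, 11 with DESeq2's size factors and 10 with library totals only (fry adjusted p = 0.555), while their share of counts was 4.20% in diapause and 4.12% outside it (exact p = 0.946). The miR-19 members of these clusters had positive values for miR-19a-3p (0.83, SE 0.50), miR-19b-3p (1.14, SE 0.46) and miR-19d-3p (1.54, SE 0.49), with 4 of 5 members positive. Their list had a fry adjusted p = 0.555, and 2 of its members passed when adjusted over the list alone. miR-101a had a log2 fold change of 0.53 (SE 0.44), and the miR-101 list a fry adjusted p = 0.827. The miR-430, miR-19, miR-29 and miR-101 lists were fixed knowing that the study's authors wrote about such families, so their counts are not independent evidence.

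**Figure D2:**
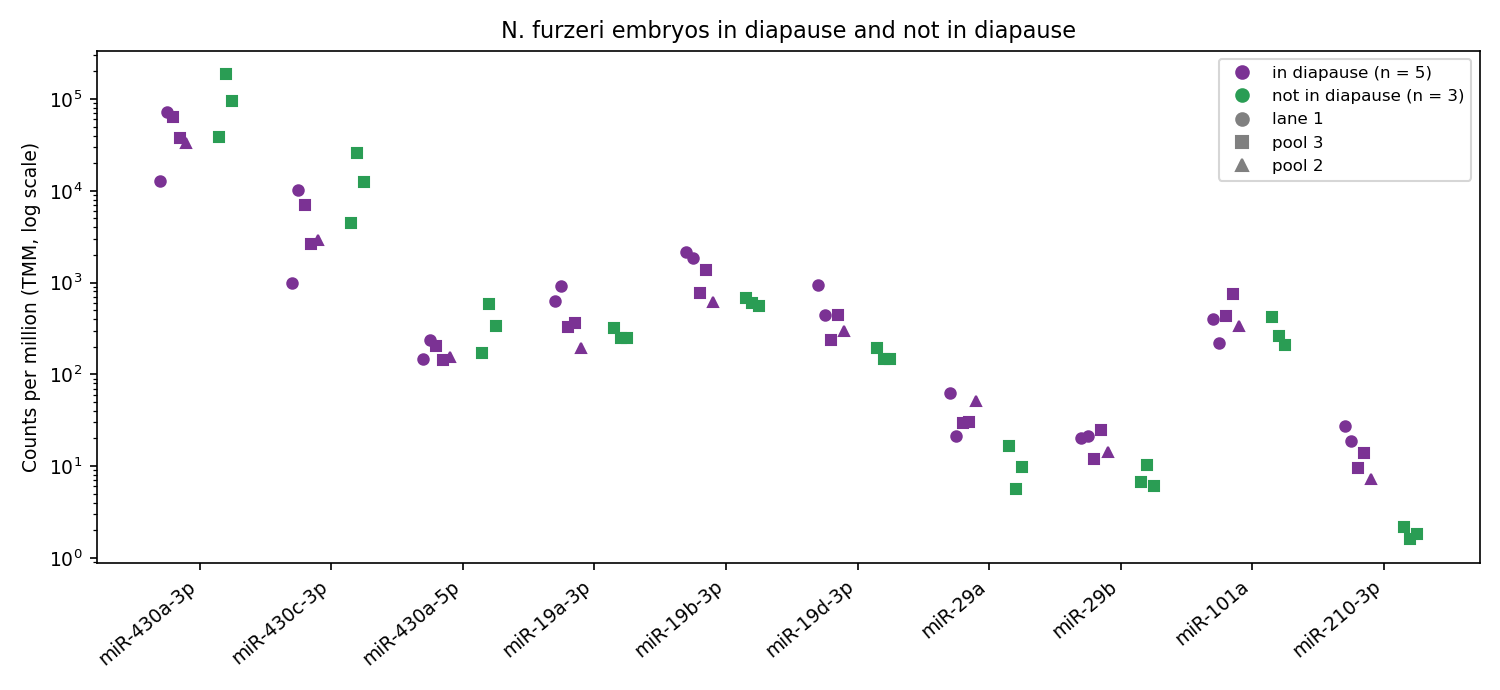
CPM (TMM scaled, log scale, y axis) of 10 miRNAs (x axis) in N. furzeri libraries in diapause (purple, n = 5) and not in diapause (green, n = 3), with point shapes for the sequencing run. miR-29a, miR-29b, miR-19d-3p and miR-210-3p showed no overlap between the groups (for miR-29a not with library totals only), and none of the 10 passed edgeR's test after adjustment; miR-210-3p was chosen after its values were seen.

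Across the 161 miRNAs tested, edgeR's quasi-likelihood test called 0, with 24 at an unadjusted p under 0.05 (13 higher and 11 lower in diapause). DESeq2 called 4 (miR-210-3p and miR-29a higher, miR-1388-3p and miR-200a-5p lower) and had 32 at an unadjusted p under 0.05. miR-210-3p, known as the miRNA induced by low oxygen and chosen here after its values were seen, averaged 15.3 ± 7.94 CPM in diapause and 1.85 ± 0.28 CPM outside it, with the lowest edgeR adjusted p of the comparison (0.0980, log2 fold change 2.98, SE 0.60). Outside diapause it had 9, 2 and 5 counts in replicates 1 to 3, near the floor, so the size of this fold is uncertain. The other tested members of the hypoxia and stress list, miR-462 (-0.66, SE 0.31) and miR-731 (-0.85, SE 0.49), had negative values, and the list did not pass fry (adjusted p = 0.827). The groups did not overlap for 14 miRNAs (8.70%, where chance gives 3.57%). Within pool 3 edgeR also called 0, with 25 at an unadjusted p under 0.05, and with sequencing run as a covariate 0, with 28. It also called 0 within strain MZM0410, with 11, with strain as a covariate, with 12, with library totals only, with 10, and without replicate 2 or 3 of the embryos not in diapause, with 10 each. None of the 27 lists passed in share of counts (lowest adjusted p = 0.941, 0 at an unadjusted exact permutation p under 0.05, smallest p possible 0.0179). A single list at that smallest p could not pass after adjustment over 27 lists, so this does not show that the shares are equal.

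N. furzeri and A. striatum, both not in diapause, were the annual and non-annual species with replicate libraries in the same state, and the comparison is of these species only. Of 157 miRNAs tested, 34 changed in edgeR's quasi-likelihood test, 12 higher and 22 lower in N. furzeri. miR-735-5p averaged 1.52 ± 0.30 CPM (SD, n = 3) in N. furzeri and 420.5 ± 193 CPM (n = 4) in A. striatum, a log2 fold change of -8.07 (SE 0.67, adjusted p = 1.07e-05). Its N. furzeri values rest on 6, 2 and 3 counts in replicates 1 to 3, near the floor, so the size of this fold is uncertain. miR-430a-5p averaged 397.1 CPM against 1.504 ± 1.74 CPM, a log2 fold change of 7.93 (SE 0.90, adjusted p = 0.000147), with 0 counts in replicates 1 and 4 of A. striatum, which allows up to 2.04 and 3.99 RPM. The opposite arm of the same hairpin, miR-430a-3p, did not pass (-1.61, SE 0.79, adjusted p = 0.161). miR-430c-3p fell from 152630 ± 106400 CPM in A. striatum to 15443 ± 11270 CPM in N. furzeri (-3.31, SE 0.80, adjusted p = 0.0135). Without A. striatum replicate 2 miR-430a-5p came to 9.02, and without its replicate 3 miR-430c-3p came to -2.71, both still called. The call of miR-430c-3p ended without replicate 1 or without replicate 3 of N. furzeri.

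miR-462 and miR-731, which share a cluster that fish induce in low oxygen and in virus infection, were lower in N. furzeri. miR-462 averaged 297 ± 77.2 CPM against 2519.7 ± 1657 CPM (log2 fold change -3.09, SE 0.55, adjusted p = 0.00367) and miR-731 had a log2 fold change of -2.95 (SE 0.65, adjusted p = 0.0120). With miR-34a, which p53 induces (-3.23, SE 0.73), the 3 tested members of the hypoxia and stress list were all called lower. They were also called when adjusted over the list alone. miR-34a had 3, 3 and 4 counts in replicates 1 to 3 of N. furzeri, near the floor, so the size of its fold is uncertain. The list's miR-210 members were not tested here. The list fell by fry (adjusted p = 0.0258 over 24 lists, 0.917 by camera with an estimated correlation). The miR-19 list also fell (fry adjusted p = 0.0258, 0.917 by camera with an estimated correlation), with 4 of 7 members called lower: miR-19b-5p (-4.57, SE 0.62, adjusted p = 0.000418), miR-19a-5p (-2.98), miR-19c-3p (-2.31) and miR-19d-5p (-1.81). Of the members given here, miR-34a and the last 3 were chosen after their values were seen. Its most abundant members did not pass, with log2 fold changes of 0.10 for miR-19b-3p and 0.17 for miR-19a-3p, which turned to -0.32 and -0.30 with library totals only. miR-19d-3p stood at -0.47 (SE 0.43). The miR-19 list took 0.110% of counts in N. furzeri and 0.168% in A. striatum (two-sided exact permutation p = 0.771). In N. furzeri replicates 1 to 3 miR-19b-5p had 7, 5 and 12 counts and miR-19a-5p 3, 2 and 7. These lie near the floor, so the size of both folds is uncertain. Whether the 5p arms differ in sequence from the counting reference was not tested.

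The miR-23/27/24 clusters, known for roles in blood vessel growth, rose in N. furzeri (fry adjusted p = 0.0354, 0.917 by camera with an estimated correlation). Of 8 members, 4 were called higher and 5 were called when adjusted over the list alone. miR-27c-3p averaged 698 ± 223.3 CPM against 153.3 ± 61.4 CPM (log2 fold change 2.19, SE 0.46, adjusted p = 0.00975), and miR-23b (3.11), miR-23a-3p (1.72) and miR-27b-5p (1.82), chosen after their values were seen, were also called. The abundant miR-27b-3p did not pass over all miRNAs (1.16, SE 0.42, adjusted p = 0.0742). The fry adjusted p of these lists lay between 0.0158 and 0.157 for the hypoxia and stress list, 0.0115 and 0.323 for miR-19, and 0.0495 and 0.167 for miR-23/27/24 when each library was left out in turn. Above 0.05 were all of the lists without replicate 1 or 3 of N. furzeri or replicate 1 of A. striatum, miR-19 and miR-23/27/24 without replicate 2 of N. furzeri or 3 of A. striatum, and the hypoxia and stress list and miR-23/27/24 without replicate 4 of A. striatum. With library totals only, miR-19 (0.182) and miR-23/27/24 (0.184) lost the call, and within pool 3 the hypoxia and stress list (0.0586) and miR-23/27/24 (0.0642) did.

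Among the other named miRNAs, those higher in N. furzeri were miR-375 of the pancreas (2.20, SE 0.59, adjusted p = 0.0194), miR-30e-3p (1.97, SE 0.59), miR-455-5p (1.83, SE 0.48) and miR-30d (1.58, SE 0.51). Those lower were miR-130c-5p (-3.04, SE 0.81), miR-22b-3p (-2.27, SE 0.56), let-7g (-2.15, SE 0.49, adjusted p = 0.0120), miR-15b-5p (-2.06, SE 0.55) and miR-181a-2-3p (-1.95, SE 0.46). With 1 library left out, miR-375 came to 1.38 (without N. furzeri replicate 1, no longer called), miR-130c-5p to -1.86 (without A. striatum replicate 4, still called), and miR-15b-5p to -2.73 (without N. furzeri replicate 1, still called). The calls of miR-375 and miR-130c-5p ended without replicate 1, 2 or 3 of N. furzeri or replicate 1 of A. striatum. That of miR-15b-5p ended without replicate 2 or 3 of N. furzeri. let-7 is known to rise as cells differentiate, and 6 of its 7 members tested had negative values, 3 of them called, while the list did not pass fry (adjusted p = 0.216). miR-101a had a log2 fold change of 1.31 (SE 0.58, adjusted p = 0.127).

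**Figure D3:**
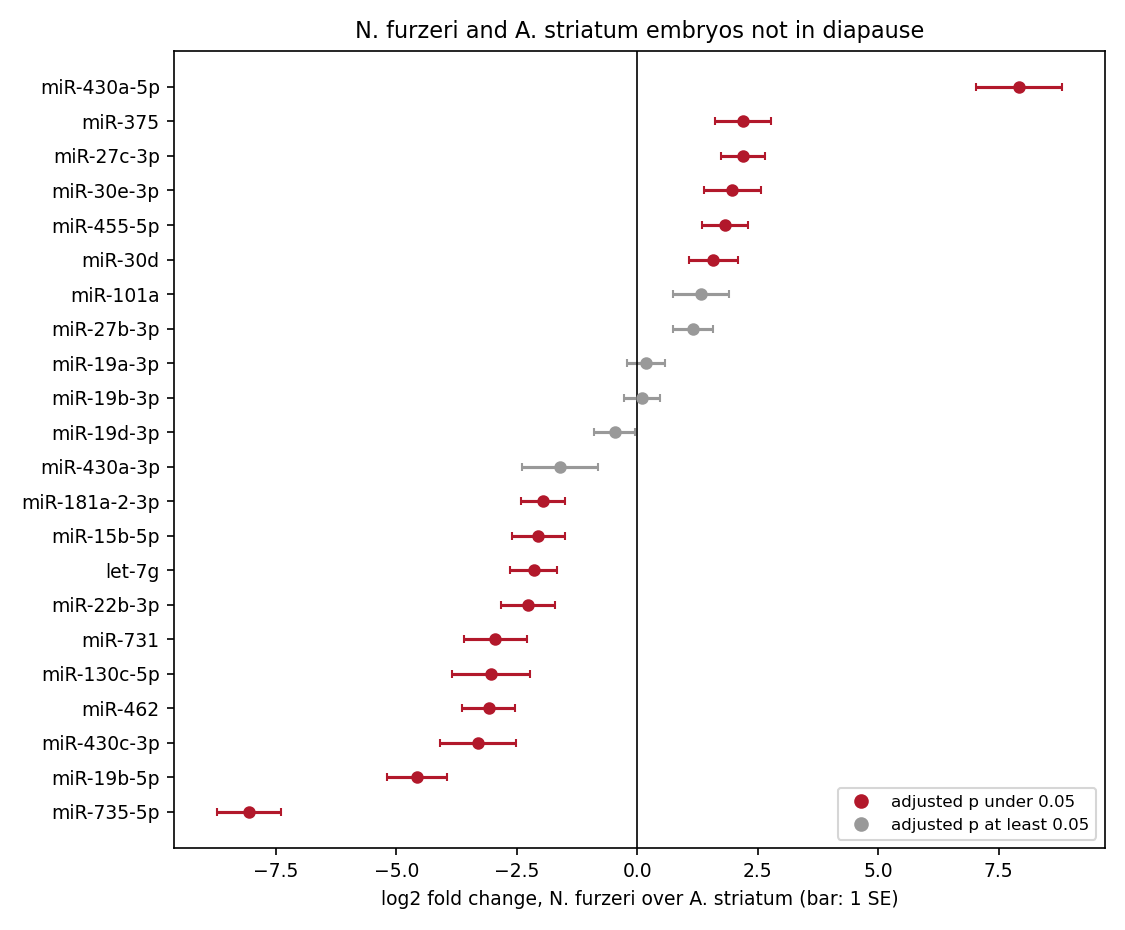
log2 fold change of N. furzeri over A. striatum, both not in diapause (x axis, bars give 1 SE), for the 22 named miRNAs (y axis); 3 N. furzeri and 4 A. striatum libraries. Red points passed edgeR's adjusted test and grey points did not, and miR-735-5p (-8.07) and miR-430a-5p (7.93) lay farthest from 0.

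The miR-430 family took 12.4% ± 8.32 (SD, n = 3) of counts in N. furzeri and 46.2% ± 14.7 (n = 4) in A. striatum, a difference of -33.9 percentage points with no overlap between the libraries. The two-sided exact permutation p was 0.0286, the smallest that 35 splits can give, and the adjusted p was 0.257 over 27 lists. Within pool 3 the difference was -31.8 points (exact p = 0.1, the smallest for 3 against 3). The miR-101 share (0.0329% against 0.0159%) and the share of miR-148 and miR-152 (0.0278% against 0.0142%) had the same exact and adjusted p, so 3 of 27 lists had an unadjusted p under 0.05 and 0 passed. With so few splits, a single list at the smallest p could not pass after adjustment over 27 lists.

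Of the 157 miRNAs, 57 had an unadjusted p under 0.05, and the libraries of the species did not overlap for 59 (37.6%, where chance gives 5.71%). DESeq2 called 38 (15 higher and 23 lower). Within pool 3 edgeR called 44 (17 higher and 27 lower), 32 of them shared with all libraries. With library totals only it called 19, of which 21.1% were higher in N. furzeri, against 35.3% with TMM, and the median log2 fold change of all miRNAs was -0.33 against 0.00. Of the 16 named miRNAs that were called, miR-430a-5p, miR-735-5p, miR-19b-5p and miR-462 were called in all 14 alternatives, of which pool 3 only and leaving out replicate 4 of A. striatum hold the same libraries. The count of calls was 7, 12 or 9 without replicate 1, 2 or 3 of N. furzeri and 18 without replicate 1 of A. striatum. These fits ended 11, 8, 11 and 5 of the 16 named calls, with adjusted p between 0.0558 and 0.154. Without replicate 2 of A. striatum the calls of miR-30e-3p (adjusted p = 0.0661) and miR-30d (0.108) ended, and without its replicate 3 that of miR-30d (0.0884). The call of miR-30d also ended with library totals only (adjusted p = 0.373), TMM without the 10 most abundant miRNAs (0.0509), no filter (0.0535) and at least 50 CPM (0.118), so it held in 4 of the 14. That of miR-455-5p ended with library totals only (0.182) and at least 50 CPM (0.0508), and with library totals only also those of miR-375 (0.168), miR-130c-5p and miR-22b-3p (0.0574 each) and miR-15b-5p (0.0546).

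The 3 annual species, all in diapause, were compared with the 5 species labelled non-annual, with the species as the replicate. Life style and diapause cannot be told apart in this comparison. Here and in the test in other species below, species were treated as independent, and their relatedness was not modelled. miR-430c-3p averaged 3622.6 ± 1516 CPM (SD, n = 3 species) in the annual species and 61189 ± 57790 CPM (n = 5 species) in the others, a log2 fold change of -4.08 (SE 1.60, edgeR adjusted p = 0.369), and miR-430a-3p had -2.94 (SE 1.40, adjusted p = 0.389). miR-430a-5p had -3.91 (SE 2.88), with 0 counts in N. papilliferus, A. leohoignei and R. cylindraceus, which allows up to 3.24, 2.75 and 8.07 RPM, and lay between -6.07 (without N. furzeri) and -1.90 (without A. lineatus) with a species left out. The miR-430 family took 2.04% ± 1.62 of counts in the annual species and 27.5% ± 25.98 in the others, a difference of -25.5 percentage points (two-sided exact permutation p = 0.143, adjusted p = 0.429). Within lane 1 the difference was -31.6 points (exact p = 0.2), and without R. cylindraceus it was -16.0 points (exact p = 0.114). With A. leohoignei, whose genus is known as annual, counted among the annual species it was -31.9 points (exact p = 0.0286). That p is unadjusted and the smallest that these groups allow. The regrouping moved a species with a share of 1.91% and was chosen after the data were examined.

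Of the miR-17-92 clusters without miR-19, 12 of 13 members had negative values, with none called, under TMM and the other scalings (median log2 fold change -0.81, fry adjusted p = 0.292). Of the miR-23/27/24 clusters, with none called, 9 of 9 had positive values with TMM scaling but 3 of 9 with library totals only (fry adjusted p = 0.292), and of the miR-100 and miR-125 family 5 of 5 with TMM but 2 of 5 with library totals only (fry adjusted p = 0.292). miR-19a-3p (0.44), miR-19b-3p (0.47), miR-19d-3p (0.63) and miR-101a (0.67) were positive with TMM and negative with library totals only, from -1.07 to -0.75. miR-19c-3p stood at -1.68 (SE 1.097). miR-29a stood at -1.88 (SE 1.52), but at 0.56 without A. leohoignei and at 2.68 with that species counted among the annual ones. The median of all miRNAs was -0.06 with TMM, -0.28 with DESeq2's size factors, -0.22 with TMM computed without the 10 most abundant miRNAs and -1.19 with library totals only.

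**Figure D4:**
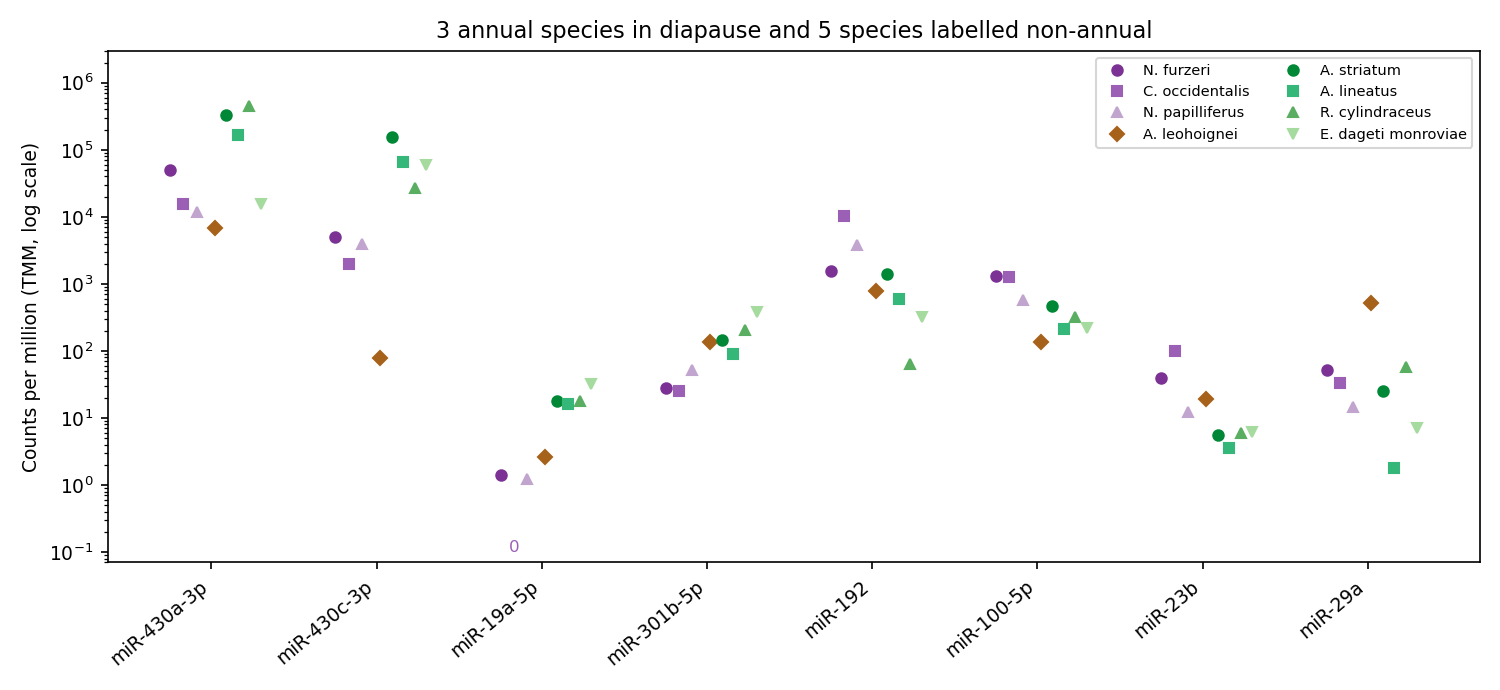
CPM (TMM scaled, log scale, y axis) of 8 miRNAs (x axis), chosen after their values were seen, in the 3 annual species in diapause (purple), in A. leohoignei (brown) and in the 4 other species labelled non-annual (green), with counts summed per species. A printed 0 marks a species with 0 counts. With TMM scaling miR-19a-5p, miR-301b-5p, miR-192 and miR-100-5p did not overlap between the annual and the 5 non-annual species. With library totals only, miR-301b-5p and miR-192 did overlap. None of the 8 passed edgeR's adjusted test.

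Of 173 miRNAs, edgeR called 0 (lowest adjusted p = 0.292), with 21 at an unadjusted p under 0.05 (7 higher and 14 lower in the annual species). DESeq2 called 8, with 33 at an unadjusted p under 0.05, and limma called 0, with 16. The DESeq2 calls were miR-192 (higher) and miR-19a-5p, miR-301b-5p, miR-430c-3p, miR-18b-3p, miR-200a-5p, miR-144-5p and miR-21 (lower). miR-192 of the gut and liver averaged 5187.2 ± 4505 CPM in the annual species and 627 ± 502 CPM in the others. With TMM scaling the species did not overlap for 11 miRNAs (6.36%, where chance gives 3.57%). Without A. leohoignei edgeR called 2, miR-19a-5p and miR-430c-3p, and with every library counted as a replicate 38. Within lane 1 it called 0, with 34 at an unadjusted p under 0.05. By fry 0 of 25 lists passed, with 4 at an unadjusted p under 0.05, and camera called 2 with its preset correlation (miR-17-92 and miR-23/27/24) and 0 with an estimated correlation. None of the 27 lists passed in share of counts (lowest adjusted p = 0.422, 0 at an unadjusted exact p under 0.05, smallest p possible 0.0179), and here too a single list at that smallest p could not pass.

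Whether miRNAs that differ between N. furzeri in and out of diapause differ in the same direction between other species was tested without any N. furzeri library. With 0 called by edgeR in N. furzeri the planned test had no members, so it was run on the 24 miRNAs with an unadjusted p under 0.05, a choice made after the data were examined. For 19 of the 24 the sign of the difference between the 2 other annual species in diapause and the 5 non-annual species was that of the N. furzeri difference, and their mean signed log2 difference was 1.01 (one-sided exact permutation p = 0.0952 over 21 choices of 2 species, smallest p possible 0.0476, highest other choice 1.41). Over all 161 tested miRNAs 121 had the same sign, with a mean of 0.74 (exact p = 0.0952).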

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

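The tests of the sequencing lane, of the share of miR-10b-5p and of the miR-430 share were chosen after the results were seen, and the test of the neural list before its value was. In the groups of 4 and 5 libraries, 15 of 93 values (16.1%) had 1 library far from all others, each time on the high side. The rule gives about 1 in 20 by chance for independent values with a symmetric, normal spread. These values come from the same libraries and were not put on a log scale, so that rate need not hold here and the excess is descriptive. Of these, 9 lay in N. furzeri diapause replicate 1. Its miR-19d-3p level was 952 CPM, against 237 to 442 CPM in the other diapause libraries. Its shares of counts (95% Wilson intervals) were 0.285% for let-7 (0.276 to 0.294%), 0.0152% for miR-29 (0.0133 to 0.0174%), 0.0795% for miR-101 (0.0749 to 0.0843%) and 0.0359% for the muscle miRNAs (0.0328 to 0.0391%). They were 0.799% for the neural miRNAs (0.785 to 0.814%), 1.14% for the sensory organ miRNAs (1.12 to 1.16%), 0.00683% for the erythroid miRNAs (0.00558 to 0.00834%) and 9.23% for miR-181 (9.18 to 9.28%).

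The other 6 lay in A. striatum. miR-462 stood at 4987 CPM in replicate 3, against 1408 to 1854 CPM in the others. miR-130c-5p stood at 991 CPM in replicate 4, against 100.6 to 242 CPM. In replicate 4 the miR-17-92 clusters took 11.05% of counts (10.98 to 11.13%), let-7 0.227% (0.217 to 0.238%) and miR-29 0.00772% (0.00597 to 0.00998%). In replicate 2 the liver and gut miRNAs took 0.288% (0.282 to 0.295%).

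N. furzeri diapause replicate 1, of lane 1 and the only library of strain MZM0403, was set apart in 6 miRNAs, among them miR-9-7-3p, miR-125a and let-7d-5p. The sequencing lane stays open. Replicate 2 of the same lane showed a median of 0.13 of the shift (quartiles 0.03 to 0.22). It is a single library, and the miRNAs were chosen for standing apart in replicate 1. A. striatum replicate 4, also of lane 1, was set apart in let-7 and miR-29 too. It held 478 counts of miR-125a, against 26, 83 and 29 in A. striatum replicates 1 to 3. For let-7d-5p it held 346 counts, against 16, 25 and 5. miR-9-7-3p was higher in the other 7 lane 1 libraries (median 113 RPM) than in the rest (median 4.18 RPM). As for the lower share of miR-10b-5p, the median shift of the 6 set-apart miRNAs was 5.35 on the log2 scale, where that share gives 0.58. They were chosen for standing apart after TMM scaling, which takes out much of such a shift. The comparison therefore covers these miRNAs only and does not decide for the library as a whole. More neural tissue may contribute and stays open, with a median log2 ratio of 1.18 over 8 neural miRNAs without miR-9 (quartiles -0.09 to 1.81, 5 of 8 positive). The strain was not tested.

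The miR-430 share was higher in every A. striatum library than in every N. furzeri library not in diapause. The sequencing run is argued against by the difference of -31.78 percentage points within pool 3. A lower level of miR-10b-5p, the most abundant miRNA on average, stays open: without it the fold of the mean shares went from 3.74 to 2.11 and the nearest libraries were at 48.2% and 54.7%, and the log2 ratio of miR-430 to other counts differed by -2.30 (95% t interval -4.86 to 0.26) against -2.86 with all counts. Earlier development of the A. striatum embryos could raise miR-430 and would lower let-7 there, yet the median log2 fold change of let-7 was -2.15, higher in A. striatum, without passing fry (adjusted p = 0.216), so this stays open. The species itself, and the match of each species to the counting reference, stay open as untested.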

How the results depend on the processing

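The alternatives on sequencing run, the left-out and run settings of the set tests, A. leohoignei as annual in the share tests, and the whole test in other species were chosen after the data were examined. For N. furzeri in and out of diapause edgeR called 0 in every alternative, and DESeq2 called 4. Its list count of 1 became 0 by camera (estimated or preset correlation), with library totals only and within pool 3, and lay between 0 and 2 with each library left out. The miR-430 difference lay between -11.32 and -3.01 percentage points with each library left out. For N. furzeri against A. striatum the count of 34 became 19 with library totals only, 17 with at least 50 CPM, where 95 miRNAs were tested, and 7 to 44 with each library left out. Its list count of 3 became 0 by camera (either correlation), 1 with library totals only, 1 within pool 3 and 0 to 5 with each library left out. miR-19b-3p turned to -0.32 and miR-19a-3p to -0.30 with library totals only, and miR-19b-3p to -0.0269 with at least 50 CPM and -0.0448 without A. striatum replicate 2, its range with each library left out being -0.0448 to 0.2449. For annual against non-annual species the count of 0 became 8 with DESeq2, 38 with every library as a replicate and 0 to 2 with each species left out, and the list count of 0 became 2 by camera with its preset correlation. With library totals only miR-19a-3p turned to -1.07, miR-19b-3p to -0.95, miR-19d-3p to -0.75 and miR-101a to -0.90. miR-29a turned to 2.68 with A. leohoignei counted as annual and to 0.56 without it, its range with each species left out being -2.44 to 0.56. The miR-430 difference was -31.89 points with A. leohoignei counted as annual (exact p = 0.0286, unadjusted and the smallest that these groups allow). The test in other species stayed above an exact p of 0.05 in every alternative, with means between 0.13 and 1.32, and could not go below it with a species left out. The cause of these changes was not tested. No miRNA name was repeated, so summing equal names did not apply, nor did settings for normalized values. For the share tests the list count has no value where 0.05 cannot be reached. No paired analysis was possible because the labels give no shared replicate numbers.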

Other observations

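The miRNAs in this part and the tests of hairpin arms were chosen after their values were seen, and the counts over other splits before. The ratio of miR-430c-3p to miR-430a-3p counts, which no scaling changes, was 0.0975 ± 0.0300 (SD, n = 5) in N. furzeri in diapause, 0.128 ± 0.0119 (n = 3) in N. furzeri not in diapause and 0.460 ± 0.0668 (n = 4) in A. striatum. It did not overlap between the latter groups (two-sided exact permutation p = 0.0286, the smallest possible), and the exact p was 0.179 between the N. furzeri groups. Single libraries ranged from 0.0118 in A. leohoignei and 0.0590 in R. cylindraceus to 3.90 in E. dageti monroviae. miR-430a-5p stood at 2466 RPM (95% Wilson interval 2378 to 2558 RPM) in A. lineatus and 2822 RPM (2682 to 2970 RPM) in E. dageti monroviae.

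Single species had high levels of particular miRNAs. In A. leohoignei miR-18c stood at 3858 RPM (3744 to 3976 RPM), miR-29a at 1457 RPM (1387 to 1531 RPM) and miR-101a at 2046 RPM (1963 to 2133 RPM), and the miR-17-92 clusters took 24.8% of counts (24.7 to 24.9%). In the other 17 libraries miR-18c lay between 4.28 and 245 RPM. In R. cylindraceus miR-31 stood at 1197 RPM (1090 to 1313 RPM), against 0.681 to 23.95 RPM in the others, and miR-150, of lymphocytes, at 436 RPM (374 to 508 RPM). miR-9-7-3p, of a family of neural progenitors, stood at 3963 RPM (3860 to 4069 RPM) in N. furzeri diapause replicate 1. It lay between 12.1 and 262 RPM in the other 7 libraries of lane 1, each of a different species, and between 0.393 and 11.6 RPM in the 10 libraries of the other runs.

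Between N. furzeri and A. striatum, miR-735-5p (-8.07) and miR-430a-5p (7.93) had the largest log2 fold changes of the named miRNAs, and for miR-430a the minor arm moved more than the major one. Over 19 hairpins with both arms tested, the excess of the minor arm's absolute log2 fold change over the major arm's was larger between the species than within N. furzeri for 9 and smaller for 10 (median difference -0.001, quartiles -0.14 to 0.48, sign-flip permutation p = 0.392), so it does not decide whether fewer reads lie behind such changes. miR-735-5p, miR-19b-5p and miR-30a-3p were not among the 19. For miR-430a the log2 fold changes of the arms lay 9.54 apart, which sequence differences from the counting reference may explain as well as a real change of arm, and these cannot be told apart without the reference sequences.

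Between N. furzeri and A. striatum only the real split, 1 of 35, gave 34 calls, and the highest other gave 1. A rank of 1 in 35 is the most extreme that these group sizes allow, so chance is unlikely but not excluded for that count. With 0 calls between N. furzeri in and out of diapause (24 at an unadjusted p under 0.05 by edgeR, 4 called by DESeq2) and 0 between annual and non-annual species (21, and 8 called by DESeq2), each of the 56 splits gives at least as many whatever the data, so this count says nothing on chance; the highest other split gave 4 and 1.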
